A study of Caenorhabditis elegans with 2 samples.

How the data were processed

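The samples were 2 biological replicates of 1 group, whole mixed-sex L1 larvae of the DPL-1::GFP strain YL425, which the labels give as separate biosamples. The labels name a library size range of 150 to 350 bp. Their antibody field names dpl-1 while their description names the GFP fusion as the target. No control or second condition was among the samples, so no test between groups was made.

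Each deposited peak list holds position, summit and a score per peak, the caller's signal value, as the authors made it. Per the deposited metadata text, the relaxed lists were called by the authors from the alignments of each replicate, or of both pooled, against a control alignment. Per the same text, the thresholded list was made from the pooled list and both replicate lists by irreproducible discovery rate. The peak caller, aligner, filters and threshold are not given in the sources used here. How signal values were scaled between libraries is also not given, so only ranks and overlaps were compared between lists. The thresholded list held exactly the 4441 strongest calls of the pooled list, so its order is that of the pooled signal. Depth per library is unknown, since the lists give no read counts, and no value here has an error from counting reads. Intervals of shares are exact Clopper-Pearson 95% intervals over peaks or genes. The interval of the replicate rho is a normal approximation after Fisher transformation, and that of the promoter odds ratio a normal approximation on the log scale (Wald). All intervals cover sampling of peaks or genes and not variation between worms.

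Lists of build ce11 were used with the WBcel235 reference sequence, whose chromosome lengths hold all calls, and with Ensembl annotation release 115. Lists of build ce10 entered only alternatives that need no annotation. A gene counted as bound when a thresholded summit lay from 1000 bp upstream to 200 bp downstream of a 5' end of a protein-coding transcript. There were 19973 nuclear protein-coding genes with 29314 distinct 5' ends, and every gene in the window of a summit was counted. Coding exons took precedence over 5' UTRs, 3' UTRs and introns when a summit was annotated, and positions outside protein-coding genes were called intergenic.

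Replicate overlap was taken over the 4441 strongest calls of each replicate with a minimum overlap of 1 bp, and compared with 1000 random placements on the same chromosomes. The promoter share was compared with 1000 placements and, by two-sided Fisher exact test, with pooled calls off the thresholded peaks. The 20 gene lists and the X chromosome were tested by two-sided Fisher exact tests against all other protein-coding genes, the lists with Benjamini-Hochberg adjustment and a threshold of 0.05. Of the written symbols, cdc-45, sld-3, rad-54 and opt-2 were not matched, and msh-4 is the gene also listed as him-14. Motifs were searched on both strands within 75 bp of each summit, in windows of 151 bp, and in windows centred 500 bp to the lower-coordinate side, with an exact McNemar test. Motif presence and signal value were related by Spearman rho with 100000 permutations.

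Named genes followed a rule written before the data were examined. These were dpl-1, efl-1, lin-35 and unc-119, all genes at the 10 strongest peaks with a gene in the window, and up to 4 strongest members per list. Members without a peak were added for lists with at most 2 of them. A result that this rule names is not reported here. Genes named as sharing a summit, klp-13 and the genes of the closing section were chosen after their values were seen. Alternatives covered each replicate alone, stricter peak sets, other promoter windows, the nearest gene only, other backgrounds, leaving out peaks with at least 50% soft-masked bases in the 200 bp around the summit, other motif windows and definitions, and build ce10. Dinucleotide-preserving shuffles (100 per window) were added after the data were seen.

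The code was tested on simulated data. All 200 genes given a planted summit were recovered (100%). A list of 50 genes, part of them planted as bound at a higher rate than other genes, was called in 100% of 20 draws. Of random lists of 50, 0.789% were called. Smaller lists were not simulated. Kept peaks were found overlapping in 100% of 1500 cases and randomly placed ones in 3.20% of 2941. A planted E2F motif was found in 100% of 800 windows, and 6.67% of 1200 windows without one held it by chance. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.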

Results

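The series measured where a tagged DPL-1 protein sat on the genome of first-stage (L1) larvae of the nematode Caenorhabditis elegans. DPL-1 is the DP partner of the E2F transcription factors, and with EFL-1 and the pocket protein LIN-35 it belongs to the DREAM complex, which is known to repress cell cycle genes. The worms, strain YL425, carried an integrated transgene with DPL-1 fused to GFP under its own promoter together with a working copy of unc-119. Chromatin of whole mixed-sex larvae was immunoprecipitated and sequenced, through the tag according to the description in the labels, although their antibody field names dpl-1. There was 1 group with 2 biological replicates and no second condition. The comparisons were therefore between the replicates, between bound and other genes, and between bound and neighbouring sequence. Each replicate had a relaxed list of 30000 calls. The pooled relaxed list held 27828 calls and the thresholded list 4441 peaks, with a median width of 340 bp. Read depth is unknown, since the lists hold no counts. The signal value of each peak is the authors' own score, and it was used to rank peaks within a list. All coordinates are of build ce11.

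The strongest DPL-1 peak lay upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control. It covered 10563341 to 10563795 on chromosome II, with an intergenic summit 168 bp upstream of a 5' end. Its signal value was 5395 in the pooled list, 3004 in replicate 1 (rank 1) and 2414 in replicate 2 (rank 3). The next peak, at 4999126 to 4999565 on chromosome II, lay between citk-2 and F59A6.11 and ranked 2 and 1 in the replicates. Ribosomal protein genes held ranks 3 (rpl-3, signal 5040) and 6 (rpl-35, signal 3738). The peak of efl-1, the E2F subunit that pairs with DPL-1, had rank 4 with a signal of 3926. It spanned 16965597 to 16966046 on chromosome V, and its intergenic summit was 170 bp upstream of efl-1 and 969 bp upstream of fbxa-90. Also among the 10 strongest were the peaks of dld-1 (rank 5), which encodes a subunit of mitochondrial dehydrogenase complexes, and cox-5A (rank 7), a cytochrome c oxidase gene. The others were at tasp-1 and K01G5.10 (rank 8), at wee-1.3 (rank 9), an inhibitory kinase of the mitotic cycle, and at rbd-1 and T23F6.3 (rank 10). In the replicates these 10 peaks ranked between 1 and 20.

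The pocket protein gene lin-35 had a peak 168 bp upstream of its 5' end, from 5807172 to 5807741 on chromosome I, with an intergenic summit that was also in the window of vps-51. Its rank was 288 in the thresholded list, 243 in replicate 1 and 365 in replicate 2. The endogenous dpl-1 gene, at 9169910 to 9172565 on chromosome II, had no thresholded peak in its promoter window. The marker gene unc-119, at 10902641 to 10908935 on chromosome III, had its strongest promoter peak at rank 2338, with the summit in a coding exon 50 bp downstream of an annotated 5' end. The replicates ranked that call 3919 and 1796. Both genes are carried on the transgene, so reads from the inserted copies could not be separated from reads of the chromosomal genes.

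The replicates shared most of their strong calls. Of the 4441 strongest calls of replicate 1, 3516 overlapped one of the 4441 strongest of replicate 2 by at least 1 bp (79.2%, exact 95% interval 77.9 to 80.4). In the opposite direction the count was 3491 (78.6%). Calls placed at random on the same chromosomes overlapped at 2.68% on average and at 3.51% at most in 1000 placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Signal values of the replicates correlated with a Spearman rho of 0.772 (95% interval 0.759 to 0.784) across the 4402 thresholded peaks with a call in both. Peaks are not independent replicates, so the interval describes these 2 libraries. All 889 peaks of the strongest group of equal size were among the 4441 strongest calls of both replicates, as were 887 of the next 888. For the weakest 888 peaks the count was 226 (25.5%, 22.6 to 28.4). These peaks lie next to a cut of the same size, so a lower count follows in part from their rank. At any rank, 4402 of the 4441 peaks had a call in both replicates. Only 41 were among the 4441 strongest calls of neither. When all 30000 calls were compared, the overlap was 45.7%, against 17.7% on average and 18.3% at most for random placements of those calls.

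DPL-1 peaks lay mainly just upstream of protein-coding genes. Of the 4441 thresholded summits, 3048 were between 1000 bp upstream and 200 bp downstream of an annotated 5' end (68.6%, exact 95% interval 67.2 to 69.996). Random positions reached 26.05% on average and 28.3% at most in 1000 placements (one-sided permutation p = 0.001, the smallest possible). Sub-threshold pooled calls lay there in 7091 of 23134 cases (30.7%, 30.1 to 31.3), an odds ratio of 4.95 (95% interval 4.62 to 5.31). The two-sided Fisher exact p was too small to be represented. The promoter share was 95.2% (93.5 to 96.5) in the strongest 889 peaks and 47.2% (43.9 to 50.5) in the weakest 888. The median summit lay 183 bp upstream of the nearest 5' end, at an offset of -183 bp, and 80.6% of summits were upstream. By annotation, 73.2% of summits were outside protein-coding genes, 20.2% in introns, 4.28% in 5' UTRs and 1.51% in 3' UTRs. Coding exons held 35 summits (0.788%, 0.550 to 1.09), against 24.6% of the genome and 13.1% of sub-threshold summits. In all, 3909 of 19973 protein-coding genes (19.6%) had a peak in the promoter window. For 1036 peaks the window of more than 1 gene was hit, so the bound gene is uncertain there.

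**Figure D1:**
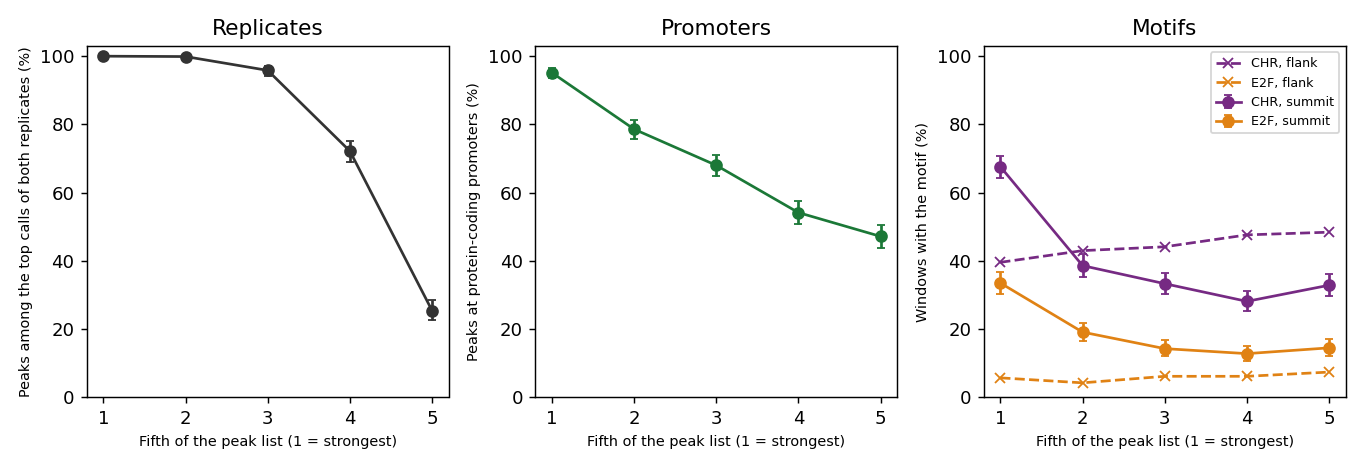
Shares of the thresholded DPL-1 peaks in 5 groups of equal size, ordered by signal value from strongest (1) to weakest (5), in percent with exact 95% intervals. Left, peaks among the 4441 strongest calls of both replicates, from 100% to 25.5%. The weak groups lie next to a cut of the same size, so this fall does not measure repeatability alone. Middle, peaks with the summit in a promoter window, from 95.2% to 47.2%. Right, windows of 151 bp with the CHR or the E2F motif at the summit (circles) or in the flank (crosses), where the CHR share falls from 67.6% to 32.9% and the E2F share from 33.5% to 14.5%.

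Promoters of genes for chromosome segregation and DNA replication were bound more often than those of other genes. In the list of centromere, kinetochore, condensin and cohesin genes, 31 of 32 members had a promoter peak (96.9%, exact 95% interval 83.8 to 99.9), against 19.4% of other genes (adjusted Fisher p = 1.29e-20). Its strongest members were kle-2 (rank 71), a condensin II subunit, knl-3 (signal 1733) and zwl-1 (rank 172) of the kinetochore, and hcp-6 (rank 142), also of condensin II. Each of these summits was also in the window of another gene (C29E4.12, T10B5.3, dot-1.1 and let-630, in that order). The 1 member without a promoter peak was dpy-28, a condensin subunit. Of the DNA replication genes, 46 of 50 were bound (92.0%, 80.8 to 97.8, adjusted Fisher p = 1.39e-27). They were led by top-2 (rank 42, summit shared with npp-3), which encodes a type II topoisomerase, pcn-1 (rank 49), the sliding clamp PCNA, rfc-4 (rank 109, shared with eef-1A.1), a clamp loader subunit, and orc-5 (rank 116), of the origin recognition complex. The peak of orc-5 was shared with cyb-1, a cyclin B gene, 500 bp from the same summit. These adjusted p-values are from two-sided Fisher exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over 20 lists. They treat genes as independent, although 1 summit can count for more than 1 gene, so very small values are not exact. The lists were fixed before the data were examined. With the 500 strongest peaks, which count fewer genes by construction, the shares of the lists above other genes were lower by over 1.5 times, except that of DREAM.

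Genes of mitosis, spindle and repair followed at lower shares. Of the mitosis and cell cycle control genes, 22 of 37 had a promoter peak (59.5%, 42.1 to 75.2, adjusted Fisher p = 2.13e-07), led by wee-1.3, sep-1 (rank 105), which encodes separase, cyb-1 (rank 116) and mdf-2 (rank 258), a spindle checkpoint gene. The centrosome, spindle and cytokinesis list had 23 of 32 (71.9%, 53.3 to 86.3, adjusted Fisher p = 4.71e-10). Its leading member was the alpha-tubulin gene tba-2 (rank 15), followed by sas-4 (rank 160), klp-18 (rank 164) and spd-1 (rank 204). For DNA damage repair the count was 28 of 42 (66.7%, 50.5 to 80.4, adjusted Fisher p = 9.76e-11), with hpr-17 (rank 34, shared with F32A11.1), polh-1 (rank 50, shared with the ribosomal protein gene rps-22), fan-1 (rank 129) and the checkpoint kinase gene chk-1 (rank 155) as strongest members. Counting only the gene nearest to each summit lowered these counts to 14, 14 and 19, and that of the kinetochore list to 20. Without soft-masked peaks the mitosis, centrosome and repair counts were 17, 20 and 18. All 4 lists were above other genes in every alternative.

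DREAM genes themselves were also bound. The list of DREAM and E2F subunits had promoter peaks at 6 of 10 members (60.0%, 26.2 to 87.8, adjusted Fisher p = 0.00757), the strongest being efl-1, lin-9 (rank 149), lin-54 (rank 168) and lin-53 (rank 215). This call was lost when only the nearest gene was counted (4 of 10, adjusted Fisher p = 0.0639). It was also lost without soft-masked peaks (4 of 10, adjusted Fisher p = 0.0638) and against genes with a pooled call in the window (6 of 9, adjusted Fisher p = 0.242). Over all 10 alternatives its adjusted Fisher p ranged from 2.86e-05 to 0.242. The summit of lin-54 was also in the window of rpl-12, a ribosomal protein gene. Among other synMuv and heterochromatin genes, 14 of 22 were bound (63.6%, 40.7 to 82.8, adjusted Fisher p = 1.39e-05). The leading members were mys-1 (rank 287), trr-1 (rank 559), lin-36 (rank 563) and lin-61 (rank 590), the last sharing its peak with bub-1, a spindle checkpoint gene. With the 500 strongest peaks, this list was no longer past the threshold (1 of 22, adjusted Fisher p = 0.605, from 6.64e-07 over the alternatives).

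Genes of protein synthesis, respiration and RNA processing were bound as well. Peaks lay at 72 of 78 ribosomal protein genes (92.3%, 84.0 to 97.1, adjusted Fisher p = 4.23e-43), with rpl-3, rpl-35, rpl-24.2 (rank 29) and rps-22 (rank 50, the peak shared with polh-1) the strongest. The shares of the ribosomal protein and replication lists did not differ detectably (odds ratio 1.04, two-sided Fisher exact p = 1, a test chosen after the data were seen). With the nearest gene only, the ribosomal protein share was lower, at 55.1% against 76% (odds ratio 0.388, two-sided Fisher exact p = 0.0237, also chosen after the data were seen). Nuclear genes of mitochondrial respiration were bound in 29 of 40 cases (72.5%, 56.1 to 85.4, adjusted Fisher p = 1.76e-12), and after cox-5A the strongest were cox-10 (rank 308), cox-14 (rank 333) and cox-6B (rank 362). The splicing and RNA polymerase II list had 33 of 41 (80.5%, 65.1 to 91.2, adjusted Fisher p = 2.71e-16). It was led by rpb-11 (rank 25), a polymerase subunit gene, snr-6 (rank 36) and snr-2 (rank 183), which encode Sm proteins of the spliceosome, and rsp-6 (rank 173), an SR protein gene. With the nearest gene only, the counts were 43, 19 and 21, each still above other genes. Without soft-masked peaks they were 55, 21 and 26, also above other genes.

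Chemoreceptor and cuticle genes were bound less often than other genes. Promoter peaks were at 14 of 1292 seven-transmembrane chemoreceptor genes (1.08%, 0.594 to 1.81, adjusted Fisher p = 1.78e-101), which are mostly used in sensory neurons. The peak at sri-5 (rank 69) was also in the window of rsr-1, that at srr-10 (rank 210) in the window of clic-1 and that at srd-4 (rank 353) in the window of usip-1. Cuticle and epidermis genes had 10 of 264 (3.79%, 1.83 to 6.86, adjusted Fisher p = 1.61e-13). The summit at col-38 (rank 66) was shared with rpl-5, that at col-2 (rank 345) with the kinetochore gene ndc-80, that at bli-6 (rank 589) with hrpf-2 and that at col-71 (rank 973) with Y49F6B.2. Counting the nearest gene alone lowered the chemoreceptor count to 7 and the cuticle count to 5. With the widest promoter window tried the counts were 28 and 17.

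Of 44 intestinal genes, 1 was bound (2.27%, 0.0575 to 12.02, adjusted Fisher p = 0.00265). This was the esterase gene ges-1, at rank 3612 in the pooled list, 16284 in replicate 1 and 2510 in replicate 2. Nuclear hormone receptor genes had 30 of 269 (11.2%, 7.65 to 15.5, adjusted Fisher p = 0.000430), led by nhr-47 (rank 652), nhr-142 (rank 824), nhr-85 (rank 1856) and nhr-228 (rank 2023). That call was lost with the nearest gene only (adjusted Fisher p = 0.109) and without soft-masked peaks (adjusted Fisher p = 0.0638), the lowest value over the alternatives being 6.31e-10. No major sperm protein gene had a promoter peak (0 of 31, upper limit of the exact 95% interval 11.2%, adjusted Fisher p = 0.00318). The list did not pass against genes with a pooled call, where 4 members remained (adjusted Fisher p = 0.181). With the 500 strongest peaks neither the sperm list (adjusted Fisher p = 0.660) nor the intestinal list (adjusted Fisher p = 0.479) passed. The lowest adjusted Fisher p over the alternatives was 0.000354 for the sperm list and 0.000219 for the intestinal list. Sperm protein and histone genes are near-identical copies whose reads may be shared or discarded, so their counts are uncertain.

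The remaining 5 lists did not pass the threshold. Meiosis and synaptonemal complex genes were bound in 12 of 38 cases (31.6%, 17.5 to 48.7, adjusted Fisher p = 0.0838), the strongest being wapl-1 (rank 223, shared with htz-1), pch-2 (rank 462), coh-3 (rank 572) and spo-11 (rank 680). Germ granule, small RNA and germline regulators had 18 of 63 (28.6%, 17.9 to 41.3, adjusted Fisher p = 0.0938), led by mes-2 (rank 54), cgh-1 (rank 88), spn-4 (rank 234) and mes-6 (rank 442). Without replicate 1 this list was above other genes (20 of 63, adjusted Fisher p = 0.0181), as it was in the stronger 2220 peaks (adjusted Fisher p = 0.0305), and the highest value over the alternatives was 0.536. Histone genes had 10 of 72 (13.9%, adjusted Fisher p = 0.312), with the strongest at his-37 (rank 695), the summit shared by his-67, his-68 and alg-5 (rank 1360) and his-72 (rank 1710). Muscle genes had 5 of 43 (11.6%, adjusted Fisher p = 0.275), led by unc-45 (rank 279), unc-112 (rank 1705), pat-6 (rank 2751) and act-4 (rank 3559). They were below other genes among genes with a pooled call (adjusted Fisher p = 0.00172, up to 1 over the alternatives). Neuronal genes had 8 of 53 (15.1%, adjusted Fisher p = 0.491), led by ehs-1 (rank 1232), snb-1 (rank 1717), rab-3 (rank 2723) and sbt-1 (rank 2772). They were below other genes in the stronger 2220 peaks (adjusted Fisher p = 0.0478, up to 0.873 over the alternatives).

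Summits shared between genes occurred in lists above and below other genes. Of all 3909 bound genes, 2048 had their strongest peak also in the window of another gene (52.4%, 50.8 to 53.97), a count made after the data were seen. The count was 50 of 72 for ribosomal protein genes, 28 of 46 for replication, 21 of 31 for the kinetochore list, 17 of 28 for repair and 27 of 33 for splicing and polymerase genes. It was 9 of 14 for chemoreceptors, 5 of 10 for cuticle genes and 5 of 30 for nuclear hormone receptors. Some genes named above without that remark also shared their summit. In lists above other genes these were sep-1, mdf-2, sas-4, klp-18, spd-1, lin-53, trr-1, rpb-11, snr-6, snr-2, cox-10, cox-14 and cox-6B. In the other lists they were nhr-47, nhr-142, coh-3, spn-4, mes-6, spo-11 and sbt-1. The gene to which DPL-1 was bound is uncertain wherever a summit is shared.

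**Figure D2:**
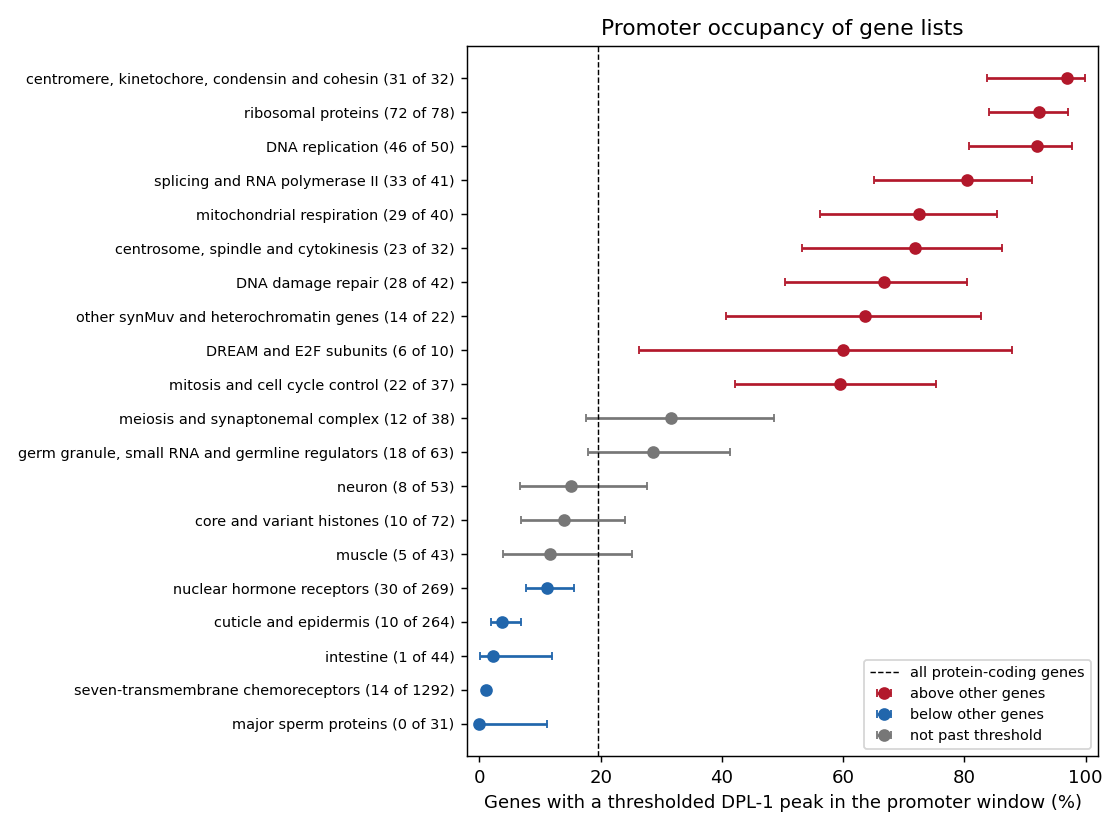
Percentage of the genes of each of the 20 lists with a thresholded DPL-1 peak in the promoter window. Points are shares with exact 95% intervals, labels give bound and total members, and the dashed line marks all protein-coding genes (19.6%). Lists above other genes (10, red) range from 59.5% to 96.9%, lists below (5, blue) from 0% to 11.2%, and 5 lists (grey) did not pass the threshold.

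The X chromosome held fewer bound promoters than the autosomes. On X, 291 of 2731 protein-coding genes had a promoter peak (10.7%, exact 95% interval 9.52 to 11.9), against 3618 of 17242 on the autosomes (20.98%, 20.4 to 21.6). The odds ratio was 0.449 (two-sided Fisher exact p = 5.13e-41). The test counts genes of 1 X chromosome and does not measure the spread between chromosomes, which ran from 12.4% to 31.7% among autosomes. The size of the difference depended on the peaks counted. Without soft-masked peaks the odds ratio was 0.619. With the stronger 2220 peaks the odds ratio was 0.271, and with the 500 strongest it was 0.0173, from 2 X-linked genes and 699 autosomal genes. The highest rank of an X-linked gene was 328, at klp-13, a kinesin gene. Autosomes also differed among themselves. Chromosomes III (31.7%) and I (29.8%) had the highest shares, II and IV had 19.3% and 19.4%, and V had 12.4% (11.5 to 13.4).

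**Figure D3:**
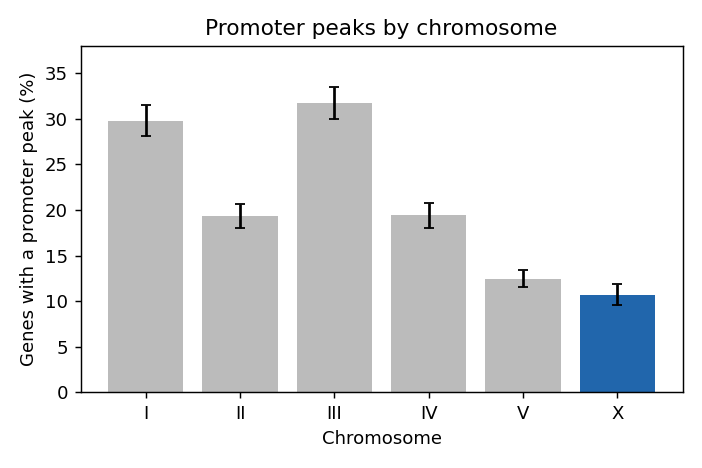
Percentage of protein-coding genes on each chromosome with a thresholded DPL-1 peak in the promoter window, with exact 95% intervals. The bar of X (10.7%) is lower than each autosome, of which V (12.4%) is the lowest and III (31.7%) the highest.

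The E2F motif was more frequent under DPL-1 summits than beside them. The sequence TTSSCGC, where S is C or G, lay within 75 bp of 838 of 4441 summits (18.9%, exact 95% interval 17.7 to 20.1) and in 265 flank windows 500 bp away (5.97%). The summit-to-flank ratio was 3.16 (two-sided exact McNemar p = 1.15e-79). The reversed sequence, used as a control, was also more frequent at summits, at 10.6% against 2.59%, and its ratio of 4.10 was above that of the motif. Summit windows had a mean GC content of 43.5% and flank windows of 36.1%. The ratio was 5.97 in the 500 strongest peaks, 4.54 in the stronger 2220 peaks, 5.09 against windows at genes without a peak and 1.88 against dinucleotide-preserving shuffles of the same windows. The last background was chosen after the data were seen. Flank windows over all peaks also exceeded shuffles of their own, at 5.97% against 5.29% at most, so an excess over shuffles was not particular to summits.

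The CHR motif, TTYGAA with Y for C or T, is the element contacted by the LIN-54 subunit of DREAM. It was at 1782 summits (40.1%, 38.7 to 41.6) and in 1979 flank windows (44.6%), so it was less frequent at summits (ratio 0.900, exact McNemar p = 3.01e-05). Its reversed control was at 14.8% of summits and 28.8% of flanks. The direction turned with strength. In the stronger 2220 peaks the ratio was 1.18 and in the 500 strongest it was 1.99. Against shuffles of the same windows, which keep base composition, the ratio over all peaks was 1.26.

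Both motifs were more common under stronger peaks. In the strongest 889 peaks the CHR motif was at 67.6% of summits (64.4 to 70.7) against 39.6% of flanks, and the E2F motif at 33.5% (30.4 to 36.7) against 5.74%. In the weakest 888 peaks the summit shares were 32.9% (29.8 to 36.1) and 14.5% (12.3 to 17.02). The reversed E2F sequence was at 16.9% and 7.32% of summits in the same groups. The E2F motif was in 15.5% and 7.14% of shuffled summit windows on average. The E2F ratio of summits to shuffles was thus 2.16 in the strongest and 2.04 in the weakest group. In the groups between, in order of strength, it was 1.74, 1.63 and 1.67. For flanks the E2F ratio to their own shuffles was 1.03 in the strongest group and 1.80 in the weakest. In the weakest group, 7.43% of flanks held the E2F motif, against 6.19% at most in shuffles. An excess over shuffles was therefore not particular to summits there. For the CHR motif the summit ratio was 1.63 and 1.15 in the strongest and weakest groups. The reversed CHR sequence was at 19.7% and 14.5% of summits. Motif presence correlated with signal value across peaks with a Spearman rho of 0.240 for the CHR motif and 0.166 for the E2F motif. The reversed controls gave 0.0475 and 0.102. The permutation p was 1e-05 for all but the reversed CHR sequence, where it was 0.00139. The value 1e-05 is the smallest that 100000 permutations can give. Adjustment over these 4 tests left it at 1e-05 when rounded to 1 digit, and 0.00139 as it was. At least 1 of the 2 motifs lay at 680 of the strongest 889 summits (76.5%) and at 2145 of all 4441 (48.3%), against 47.98% of all flank windows.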

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

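Replicate 2 had 21 calls on the mitochondrial chromosome, which the comparisons of nuclear genes did not use. Replicate 1, the pooled list and the thresholded list had 0 there. All 21 were among the 4441 strongest calls of replicate 2, the strongest at rank 98. The value stood out because it is above the 3 calls that a count of 0 allows. No explanation was tested.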

How the results depend on the processing

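Of 275 recomputed values, 68 of main results and 186 of single lists kept their direction and side of the threshold or stayed within their limit. The motif shuffles were chosen after the data were seen. Leaving out a replicate kept the promoter share at 66.9% to 69.6%, the X odds ratio at 0.461 to 0.489 and the E2F ratio at 2.93 to 3.40. The CHR ratio was then 0.898 to 0.914, and 10 to 11 lists were above and 5 below other genes. Replicate overlap and rank agreement need both replicates and have no such value. The CHR ratio turned to 1.18 in the stronger 2220 peaks, 1.99 in the 500 strongest and 1.26 against shuffled windows. With the 500 strongest peaks, 3 lists were below other genes in place of 5 and the rank correlation was 0.746 in place of 0.772. The difference between strongest and weakest group was 24.0 percentage points for the E2F motif and 44.0 for the CHR motif with 10 groups by strength, against 18.99 and 34.7 with 5. The 10 groups compare fewer and more extreme peaks. With the nearest gene only, the neuron list (15.1%) moved from below to above other genes (14.5%), without passing the threshold in either case. For the other changes the cause was not tested. Among single lists, 9 calls were lost and 4 gained. Chromosome lengths of ce10 were not used here, so X was compared between builds as a share of peaks, 10.02% in ce11 and 9.97% in ce10. How far read depth limits the weak peaks is unknown, since no counts are held. The weakest 888 peaks were among the strongest calls of both replicates in 25.5% of cases, a share that also reflects their place next to the cut.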

Other observations

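The gene classes, noncoding genes and direct comparisons of lists in this part were chosen after the data were seen, as were the tests of the CHR motif, of unc-119 alone and of ribosomal protein against replication genes with the nearest gene only. The other tests of ribosomal protein peaks and of both transgene genes were written before their results were seen.

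Beyond the fixed lists, gene classes were formed from shared symbol prefixes with at least 10 members, leaving out listed genes. Of 137 classes, 19 were above and 19 below other genes (two-sided Fisher exact tests, Benjamini-Hochberg adjusted). Nucleoporin genes (npp) had promoter peaks at 24 of 26 members (92.3%, adjusted Fisher p = 1.39e-13), among them npp-19 at rank 35. Proteasome regulatory subunit genes (rpn) had 12 of 13 (adjusted Fisher p = 9.10e-07) and translation initiation factor genes (eif) 21 of 25 (adjusted Fisher p = 3.23e-10). Integrator subunit genes (ints) had 9 of 11 (adjusted Fisher p = 0.000134). Mitochondrial ribosomal protein genes had 25 of 41 (mrpl, adjusted Fisher p = 2.37e-07) and 19 of 29 (mrps, adjusted Fisher p = 1.71e-06). C-type lectin genes (clec) had 6 of 240 (2.50%, adjusted Fisher p = 1.39e-13), neuropeptide-like genes (nlp) 1 of 70 and transthyretin-related genes (ttr) 0 of 58.

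Noncoding gene classes differed in how often they lay near summits. Of 612 tRNA genes, 175 had a thresholded summit within 200 bp (28.6%, exact 95% interval 25.04 to 32.4), against 1.80% on average and 3.10% at most in 100 random placements. The 164 peaks concerned were weak to moderate, with the strongest at rank 1012. Of these, 121 lay off protein-coding promoter windows, and 47 were in the weakest of the 5 strength groups. Among the 4441 strongest calls of both replicates were 105 (64.02%), against 78.7% of all thresholded peaks. An E2F or CHR motif lay at 33.5% of the tRNA peaks and at 48.9% of other peaks. Peak strength was not matched in either comparison. The tRNA peaks had a median rank of 3055.5, and 0 were in the strongest group, where 76.5% of peaks held a motif. In the third to the weakest group the motif share of all peaks was 40.4%, 36.4% and 40.4%. Small nucleolar RNA genes had 88 of 346 (25.43%, 20.9 to 30.4), against 5.78% at most when placed. Small nuclear RNA genes had 18 of 129 (13.95%, 8.48 to 21.2), against 6.20%. Genes of piRNAs had 48 of 15363 (0.312%) against a placed mean of 1.79% and a highest of 2.16%, and pseudogenes 38 of 2128 (1.79%) against 7.36% and 8.5996%. Genes of the annotated type ncRNA had 673 of 7764 (8.67%), against 2.72% at most when placed. Other classes not above the highest placement were antisense RNA (6 of 100, 13% at most), lincRNA (25 of 194, 14.4%), miRNA (13 of 261, 5.36%) and rRNA (0 of 20, 15%). The placements were uniform along each chromosome and did not keep the preference of summits for protein-coding promoters. Peaks off promoter windows were counted for tRNA genes only. For the other classes a difference from placements cannot be told apart from their position relative to protein-coding promoters.

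Ribosomal protein promoters were bound at a share close to that of replication promoters (92.3% and 92%), yet an E2F or CHR motif lay at 27 of 70 ribosomal protein peaks (38.6%) and at 43 of 50 replication peaks (86%, two-sided Fisher exact p = 2.09e-07). All 72 bound ribosomal protein genes (100%) had their strongest peak among the strongest calls of both replicates. Strong pooled peaks met the same criterion at any gene. All 889 of the strongest group did, and 50 of the 72 genes had their peak there. Of all thresholded peaks, 78.7% met it. Calls not repeated between replicates were therefore only weakly tested as an explanation. With the nearest gene only, 55.1% of ribosomal protein genes were bound, more than other genes but fewer than replication genes (76%, odds ratio 0.388, two-sided Fisher exact p = 0.0237), so peaks of neighbouring genes do not account for all of the occupancy but may account for the close shares. The 38.6% was below the mean of shuffled windows (43.4%) and respiration peaks were below theirs (25.8% against 42.8%), while replication peaks exceeded the highest of 100 shuffles (70%), as did splicing and polymerase peaks (96.8% against 77.4%). A candidate explanation for ribosomal protein peaks is signal at open promoters without contact to either motif. Its rule asked for a share not above the 95th percentile of shuffles (52.9%), which the 38.6% met. Contact through another sequence or protein would give the same result, so the comparison cannot tell them apart and both remain open. Neither was tested beyond the motif share.

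The CHR motif was less frequent at summits (40.1%) than in flanks (44.6%) over all peaks, and in 100 of 100 shuffles the summit windows had a lower share than the flank windows, so the GC content of summits (43.5% against 36.1%) may account for the lower share. Absence of the element has values against it in the strongest 3 of the 5 strength groups, where 67.6%, 38.6% and 33.3% of summits held it and the highest of 100 shuffles reached 45.8%, 35.2% and 32.3%, while 62, 15 and 19 shuffles of their flanks were as large as the flanks. The weakest group also exceeded its shuffles (32.9% against 31.8% at most), but so did its flanks (48.4% against 46.96%). In the fourth group, where the share was 28.2%, 33 of 100 shuffles were as large, and absence remains open there. No further explanation was tested.

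Calls ran along unc-119, which the transgene carries, and not along dpl-1, which it also carries. With 1000 bp on both sides, unc-119 had 10 pooled calls and 5 thresholded peaks, and its 1.21 calls per kb put it at percentile 99.2 of protein-coding genes, a density that 0 of 53 neuronal genes reached. Extra copies of unc-119 on the transgene may account for this. For both genes together that account cannot be told apart from others, since dpl-1 had 0 calls in the pooled list and in either replicate (percentile 37.1, shared by all genes with 0 calls), and the strain behind the control alignment is not given in the sources used here. No biological explanation was tested.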
